A study of Homo sapiens with 4 samples.

How the data were processed

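Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used in the human cell line H69 to map DNA bound by YAP, a transcriptional coactivator of the Hippo pathway, and by TEAD1, a DNA-binding partner of YAP. Per the labels' protocols, cells were crosslinked with formaldehyde, and the chromatin was sheared by sonication. The series holds 4 libraries, 1 per antibody. They were made with an unrelated IgG, a YAP antibody from Santa Cruz, a further YAP antibody and a TEAD antibody. The labels name the last antibodies only as YAP and TEAD. The design text of the series names them as Avruch and TEAD1, and these names are used here. The IgG library was not analysed here, because no processed file of it was used.

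The values analysed were 3 deposited peak lists, 1 per library, each with 5 columns and no header. Reads were aligned with Bowtie2 to the human genome build hg19, per the submitters' processing notes. The peak names in the deposited lists carry the name of the peak caller MACS. Its version and settings, the control library used, and the handling of duplicate reads or problem regions are not given in the sources used here. The deposited score of each peak is the authors' own value and has no stated unit. Scores were used only to describe, rank or filter peaks within a list. Read depth is not given in the peak lists, so differences in the number of peaks between libraries cannot be separated from differences in depth. If the same IgG library served as the control of all 3 lists, part of their overlap could come from it, and this was not simulated.

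Peak lists were compared by position, with an overlap of at least 1 bp counted as shared. Each share has a Wilson 95% interval, which covers counting error only. Each overlap was compared with 1000 random placements of the first list's peaks on their own chromosomes, within the range spanned by all peaks of that chromosome and with assembly gaps left in. The p-value is one-sided and counts placements at or above the observed share, so the smallest value that 1000 placements can give is 0.000999. With 1 library per antibody, these p-values describe the libraries and not a population of experiments. As an alternative, each peak was moved by 10 to 100 kb to a random side, which is called a local move here. Moves were not stopped at the ends of contigs or chromosomes or at long peak-free stretches. Moved peaks could therefore land where no peak lies, which can make the shares after local moves too low, above all within repeat-like regions, defined below. Ratios of median scores and differences between shares have 95% intervals from 1000 bootstrap draws of 5 Mb genome blocks, and a call was made where the interval left out no change. TEAD1 clusters were runs of at least 3 peaks with gaps of at most 10 kb. The comparisons, their tests and the variations of the settings were fixed before the data were examined. These variations were the 50% of peaks with the highest scores, lists of equal length, an overlap of 50% of both peaks, windows of 200 bp, local moves, autosomes alone, other cluster gaps, and YAP peaks found with both antibodies. For the numbers of peaks, joining of peaks with gaps of at most 1 kb was a further variation.

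Further choices were made after the lists had been seen. Many of the highest-scoring peaks were wide and lay beside long stretches without peaks. Repeat-like regions were therefore defined from the lists alone. They comprised unplaced or unlocalised contigs, 26 stretches of at least 2.5 Mb without a peak in any list with 2 Mb to each side, and any peak at least 1 kb wide with 50 kb to each side. They merged into 189 regions on the placed chromosomes, with a total length of 338.2 Mb. This length includes the peak-free stretches, so it gives no basis for a density of peaks. Wide peaks lie inside by this construction, and no repeat annotation was used, so the name describes peak shape and position only. A further definition left out 139 windows of 200 kb that held more than 5 peaks of a YAP list. This one is drawn from the YAP lists themselves, so it removes YAP sharing by construction. Within dense windows of at least 10 Avruch peaks, distances of 1 to 20 kb between peaks were counted in bins of 200 bp. The fullest bin was compared with the 95th percentile of 200 random placements over the window and, separately, of 200 moves of each peak by up to 2 kb. In comparisons within or outside these regions, the first list was restricted and the other list was kept whole. Sharing was also compared over 20 equal bins of TEAD1 score. The contrast of the strongest 5% of TEAD1 peaks with the next 25% was picked after these bins had been seen, and the strongest 10% against the rest is given beside it.

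The genes nearest to peaks, the distance to transcription start sites, TEAD and AP-1 motifs and the fixed gene lists were planned. They were not run, because no genome or annotation of build hg19 was used here. The fallback rule, fixed beforehand, names the positions of the 5 highest-scoring peaks of each list, with ties in file order. Positions on the Y chromosome are not listed. Positions named under any other rule were chosen after their values had been seen. Coordinates are counted from 1. In the TEAD1 list, 2 peaks began before the first base of their chromosome and were kept.

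Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The functions were tested on simulated data. A planted overlap of 30.0% in 5000 peaks was recovered as 30.0%, and planted clusters holding 40.0% of 1000 peaks were recovered as 40.0%. The fast count of mutual overlaps gave 259 peaks, as did a brute-force count. Block bootstrap intervals held a planted ratio of medians in 95.0% of 40 simulated draws. Groups and scores were drawn independently for each peak, so dependence between neighbouring peaks was not tested.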

Results

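Peaks from 3 ChIP-seq libraries of H69 cells, each without a replicate, were compared to ask where YAP was found with either of its antibodies and how far these sites coincided with TEAD1. The TEAD1 list was the longest, with 48962 peaks. The Avruch antibody against YAP gave 10118 peaks and the Santa Cruz antibody 2471. Median peak width was 274 bp for TEAD1, 149 bp for Avruch and 167 bp for Santa Cruz. Together the peaks covered 16396.1 kb, 2471.32 kb and 1136.13 kb. Scores began at about 50 in each list, with a median of 67.1 for TEAD1, 63.8 for Avruch and 59.2 for Santa Cruz. They are the authors' values, have no stated unit and are not compared between lists. As read depth was not known, the numbers of peaks do not rank the proteins by how widely they were bound.

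The highest-scoring YAP peaks were at least 1 kb wide and lay on unplaced or unlocalised contigs or beside long peak-free stretches. The Santa Cruz list was led by a peak 35653 bp wide on the unplaced contig Un_gl000220 (hg19, 116859 to 152511, score 3095.31). It was followed by a peak on 19_gl000208_random (88236 to 89257, score 2108.13), one on chromosome 17 (22247035 to 22262560, score 1753.38), one on chromosome X (58564717 to 58582013, score 1608.57) and a further peak on Un_gl000220 (101455 to 108643, score 1575.77). In the Avruch list, the leading peaks lay on chromosome 2 (92315206 to 92326175) and chromosome X (58564723 to 58582011), both with a score of 3100. The other listed Avruch peaks lay on chromosome 10 (42386910 to 42397392, score 2287.04) and Un_gl000220 (101509 to 107992, score 1633.28). The chromosome X peak was common to both antibodies and had no TEAD1 peak.

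The TEAD1 list had narrow peaks near its top. Its highest score, 3219.44, belonged to a peak on Un_gl000220 (112943 to 116643) that overlapped peaks of both YAP lists. The next peaks were 657 bp wide on chromosome 9 (114792172 to 114792828, score 3139.81) and 596 bp wide on chromosome 11 (128387447 to 128388042, score 3133.14). Neither overlapped a YAP peak of either antibody. Then came 22 peaks tied at 3100, of which the first in file order were wide neighbours on chromosome 1 (228744016 to 228762749 and 228762752 to 228782526), both shared with both YAP lists. Which genes lie at these positions was not analysed here.

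Repeat-like regions held 38.4% of Santa Cruz peaks (948 of 2471, Wilson 95% interval 36.5 to 40.3), 22.3% of Avruch peaks (2252 of 10118, 21.5 to 23.1) and 7.47% of TEAD1 peaks (3658 of 48962, 7.24 to 7.71). Peaks at least 1 kb wide made up 52.3% of the base pairs covered by Santa Cruz peaks, 24.0% for Avruch and 8.20% for TEAD1. The definition of these regions takes in every peak at least 1 kb wide, and so the leading YAP peaks. Among the peaks left outside, the highest score was 282.0 in the Santa Cruz list, where the maximum had been 3095.31, and 480.3 in the Avruch list, where it had been 3100.

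Peaks of the YAP antibodies overlapped far more often than randomly placed peaks did. Of the Santa Cruz peaks, 697 of 2471 (28.2%, 26.47 to 30.01) overlapped an Avruch peak, against a mean of 3.08% and a maximum of 4.09% over the random placements. Of the Avruch peaks, 826 of 10118 (8.16%, 7.65 to 8.71) overlapped a Santa Cruz peak, against a mean of 0.943% and a maximum of 1.19%. On autosomes alone, the observed shares were 23.8% for Santa Cruz and 6.37% for Avruch, against random means of 0.209% and 0.0496%. Most of the overlap in random placements thus came from other chromosomes and contigs. In all regions, both comparisons gave a one-sided permutation p = 0.000999 by random placement, the smallest that 1000 placements can give. Such placement ignores uneven peak density, so density of any source common to the lists can give these values. Most of the sharing between the antibodies lay in repeat-like regions, which held 603 of the 697 shared Santa Cruz peaks (86.5%, 83.8 to 88.9). Within them, 63.6% of Santa Cruz peaks overlapped an Avruch peak (60.5 to 66.6, highest of the local moves 15.8%, possibly too low). Outside them, 94 of 1523 did (6.17%, 5.07 to 7.49), against at most 1.05% in the local moves. Repeat-like regions are drawn partly from wide YAP peaks, so the contrast between inside and outside is partly set by construction. With an overlap of 50% of both peaks required, the shares in all regions were 18.4% for Santa Cruz and 4.50% for Avruch, and with the 2471 highest-scoring peaks of each list they were 22.0% and 24.6%.

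**Figure D1:**
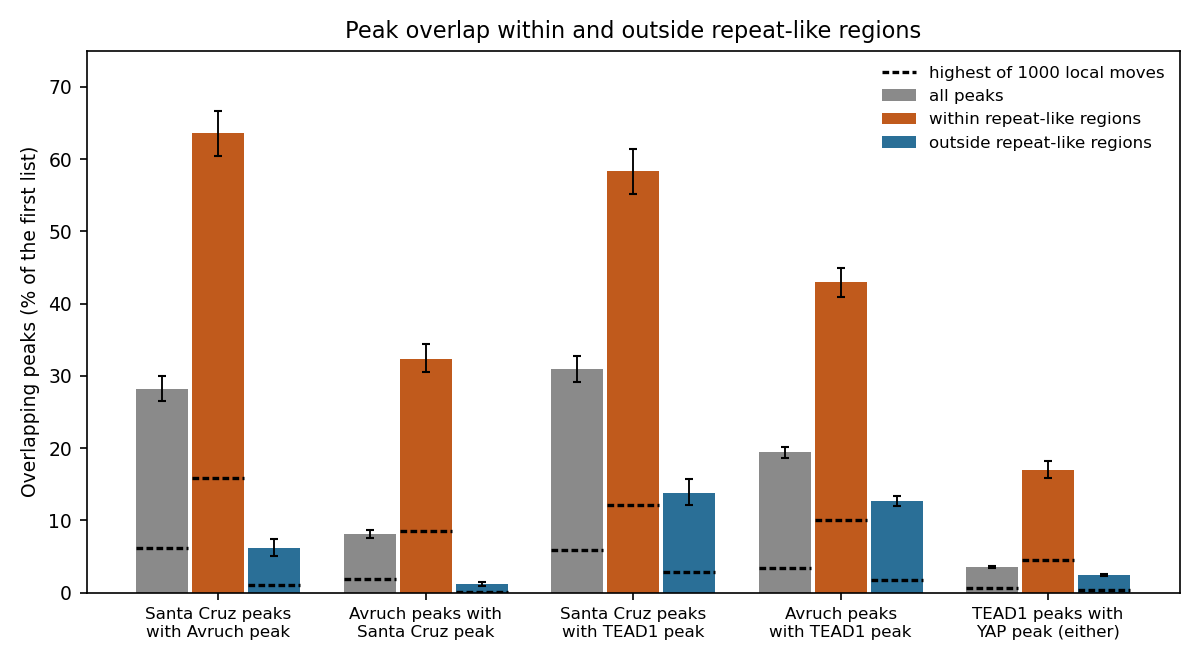
Share of peaks of the first-named list that overlapped the second (%), for all peaks, peaks within and peaks outside repeat-like regions of 3 unreplicated libraries; error bars are Wilson 95% intervals and dashed lines the highest of 1000 local moves. Santa Cruz peaks overlapped an Avruch peak at 63.6% within and 6.17% outside these regions, and each share exceeded the dashed line. Moves could leave a contig or enter a peak-free stretch, so the dashed lines may lie too low within these regions. The regions are drawn partly from wide peaks of these lists, so the contrast is partly set by construction.

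YAP peaks also coincided with TEAD1 peaks. TEAD1 peaks overlapped 764 of the 2471 Santa Cruz peaks (30.9%, 29.1 to 32.8, random mean 2.59%, maximum 3.52%). They overlapped 1964 of the 10118 Avruch peaks (19.4%, 18.7 to 20.2, random mean 1.64%, maximum 2.03%). Seen from the TEAD1 list, 1759 of 48962 peaks carried a YAP peak of either antibody (3.59%, 3.43 to 3.76, random mean 0.336%, maximum 0.425%). Each of these gave a permutation p = 0.000999 by random placement, which ignores uneven peak density. Density of any source common to the lists can therefore give such values, and they do not measure binding together. The highest shares after local moves were 5.87% for Santa Cruz, 3.44% for Avruch and 0.629% for the TEAD1 list. The remaining 47203 TEAD1 peaks (96.4%) overlapped no YAP peak, and 7854 Avruch peaks (77.6%) and 1477 Santa Cruz peaks (59.8%) overlapped neither of the other lists. Only 323 TEAD1 peaks overlapped both YAP lists, of which 259 lay in repeat-like regions.

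Outside repeat-like regions, the overlap with TEAD1 was 13.9% for Santa Cruz (211 of 1523, 12.2 to 15.7, highest local move 2.82%) and 12.7% for Avruch (997 of 7866, 12.0 to 13.4, highest local move 1.82%). Of the TEAD1 peaks outside, 2.51% carried a YAP peak (1137 of 45304, 2.37 to 2.66, highest local move 0.377%). Within repeat-like regions, the overlap with TEAD1 was 58.3% for Santa Cruz and 42.9% for Avruch. As these regions are drawn partly from wide peaks of the lists, this contrast too is partly set by construction. With an overlap of 50% of both peaks required, TEAD1 peaks overlapped 8.17% of all Santa Cruz and 5.73% of all Avruch peaks, and 1.47% of TEAD1 peaks carried a YAP peak, each still above its random maximum. TEAD1 peaks were wider (median 274 bp, against 167 bp for Santa Cruz and 149 bp for Avruch). A YAP peak wholly inside a TEAD1 peak can therefore fail this rule, so part of the fall reflects width. With the 2471 highest-scoring peaks of each list, 16.9% of Santa Cruz and 17.2% of Avruch peaks overlapped a TEAD1 peak, and 10.5% of TEAD1 peaks carried a YAP peak.

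In the window of 200 kb with the most Avruch peaks, on chromosome 4 from 9213414 to 9370712, 106 Avruch peaks stood beside 9 Santa Cruz and 8 TEAD1 peaks. None of the Avruch peaks there lay in a repeat-like region as defined here. Distances between them recurred most often near 4726.5 bp, in 36 pairs. The 95th percentile was 28 pairs for random placement over the window (maximum 32) and 33 for moves of each peak by up to 2 kb (maximum 39). With windows dense in YAP peaks left out in addition to repeat-like regions, the share of Santa Cruz peaks overlapping an Avruch peak went from 6.17% to 4.88% (71 of 1456, 3.88 to 6.11).

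**Figure D2:**
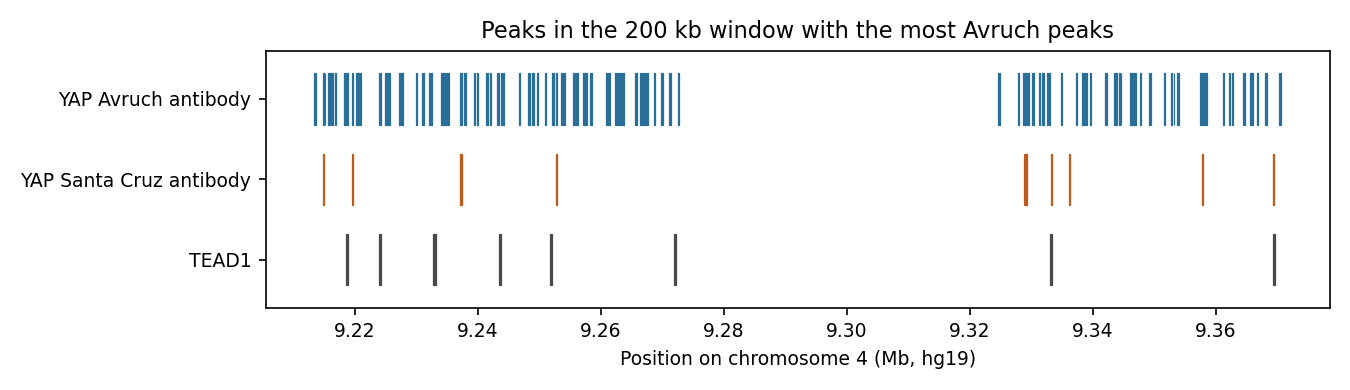
Peaks of the Avruch, Santa Cruz and TEAD1 lists along chromosome 4 (Mb, hg19), in the 200 kb window with the most Avruch peaks. Each bar is 1 peak, drawn to scale except for a thin outline. The 106 Avruch peaks lie in dense blocks with few Santa Cruz or TEAD1 peaks among them.

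TEAD1 peaks with a YAP peak had higher TEAD1 scores than those without. The median score was 87.3 over 1759 peaks with YAP and 66.6 over 47203 without, a ratio of 1.31 (block bootstrap 95% interval 1.24 to 1.40). The ratio was 2.89 within repeat-like regions (2.22 to 3.78) and 1.13 outside them (1.09 to 1.15). With YAP counted only where both antibodies gave a peak, the median was 336.8 over 323 TEAD1 peaks, and the ratio was 5.03 (3.56 to 6.95). Of these 323 peaks, 259 lay in repeat-like regions, where the ratio by this count was 6.01 (4.31 to 8.20), and for the 64 outside it was 1.79 (1.48 to 2.03). For YAP peaks of either antibody in all regions, the ratio was 1.20 with windows of 200 bp (1.15 to 1.26) and 1.09 with an overlap of 50% of both peaks (1.04 to 1.14). The latter rule also leaves out narrow YAP peaks inside wide TEAD1 peaks. TEAD1 width rose with score, from a median of 242 bp in the lowest of 20 score bins to 546 bp in the highest. Wider peaks overlap others more easily. No ratio with equal windows was computed for both antibodies together or by region, so width may contribute to those ratios.

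Sharing was also followed over 20 equal bins of TEAD1 score, a comparison added after the lists had been seen. Counting all regions, Avruch sharing was 1.51% in the lowest bin, 4.58% in bin 19 and 11.4% in the highest bin (10.2 to 12.7). Santa Cruz sharing was 0.367%, 2.78% and 8.66% (7.61 to 9.84). Outside repeat-like regions, Avruch sharing was 1.41% in the lowest bin, 3.89% in bin 17 (3.16 to 4.76) and 1.59% in the highest bin (1.15 to 2.19). Windows dense in YAP peaks were then also left out, a filter that removes YAP sharing by construction. Avruch sharing was then 1.35% in the lowest bin, 3.46% in bin 17 (2.77 to 4.30) and 1.35% in the highest bin (0.945 to 1.92). Santa Cruz sharing there was 0.224% in the lowest bin, 1.17% in bin 18 (0.798 to 1.71), 1.03% in bin 19 and 0.763% in the highest (0.477 to 1.22), and the intervals of these last bins overlapped.

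**Figure D3:**
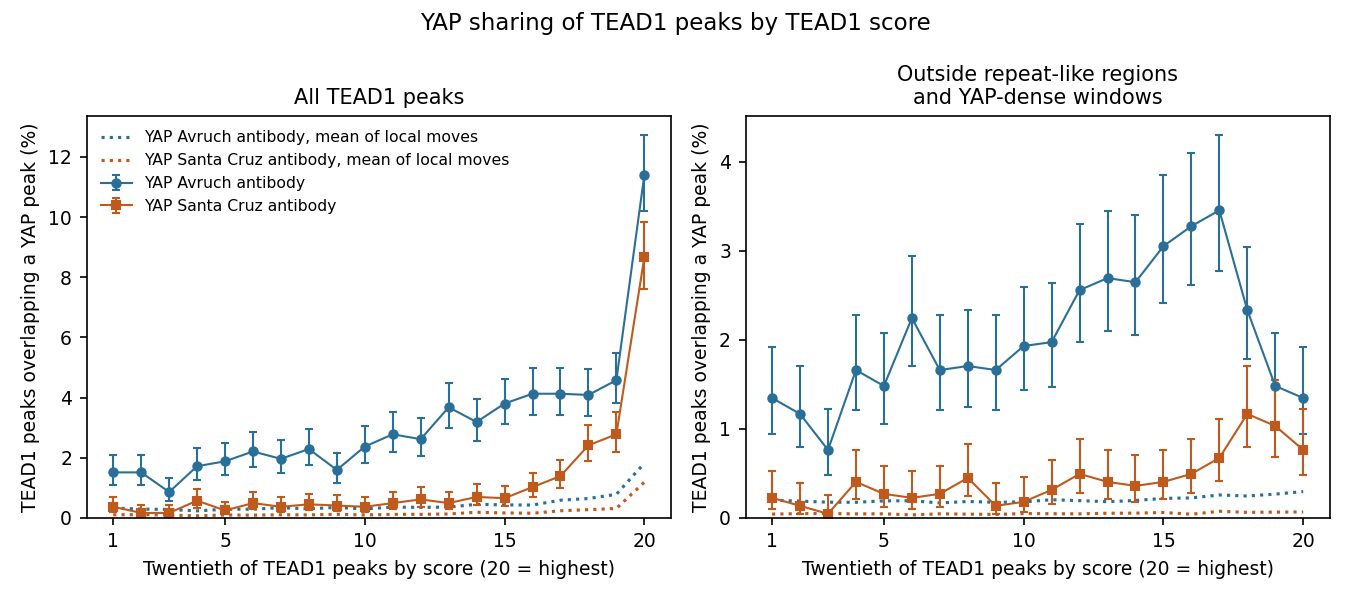
Share of TEAD1 peaks overlapping a YAP peak (%) in 20 equal bins of TEAD1 score, for the Avruch and Santa Cruz antibodies, in all regions (left) and outside repeat-like regions and YAP-dense windows (right, other scale). Error bars are Wilson 95% intervals and dotted lines means of 100 local moves, and the highest bin reached 11.4% for Avruch on the left and 1.35% on the right. The filter on YAP-dense windows removes YAP sharing by construction.

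The title of the series names super-enhancers, which are clusters of bound sites, so clustering of TEAD1 peaks was measured. Of the TEAD1 peaks, 14339 (29.3%, 28.9 to 29.7) lay in 3263 clusters of at least 3 peaks, the largest with 68. Random placements gave a mean of 8.85% and a maximum of 9.52% (permutation p = 0.000999). Outside repeat-like regions, 26.6% of TEAD1 peaks were clustered (26.22 to 27.03, random maximum 8.31%), in 2951 clusters of which the largest held 35 peaks. Random placement spreads peaks evenly over each chromosome, also over the regions left out here. Uneven peak density of any source therefore raises the observed share above it. Peaks close together count separately, and joining those with gaps of at most 1 kb leaves 43918 TEAD1 peaks. No Mediator or histone data were used here, so the clusters are not called super-enhancers. The clustered share was 17.2% with gaps of at most 5 kb and 46.8% with gaps of at most 20 kb.

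Clustered TEAD1 peaks carried an Avruch peak more often than TEAD1 peaks outside clusters, pairs included, when all regions were counted. The shares were 4.73% in clusters and 2.44% elsewhere, a difference of 2.28 percentage points (block bootstrap 95% interval 1.29 to 3.47). Within repeat-like regions the difference was 11.3 percentage points (6.06 to 17.2). Outside these regions the shares were 2.10% in clusters and 2.22% elsewhere, a difference of -0.125 percentage points whose interval (-0.611 to 0.452) included 0. Clusters were drawn anew within and outside. Repeat-like regions are drawn partly from wide peaks of the lists, so restricting by them acts on the sharing, and the cause was not tested. For Santa Cruz, the shares outside these regions were 0.614% in clusters and 0.406% elsewhere, a difference of 0.207 percentage points (0.0266 to 0.396), against 2.08 in all regions (1.40 to 2.91). With windows dense in YAP peaks also left out, a filter that removes YAP sharing by construction, the difference was 0.0747 percentage points for Santa Cruz, with an interval that included 0 (-0.0598 to 0.211), and -0.679 for Avruch (-0.982 to -0.375).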

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

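All tests in this part that restrict regions, compare TEAD1 score classes or compare the antibodies with each other were chosen after the values had been seen; the comparison of clustered with other TEAD1 peaks for the Avruch antibody was planned. This holds also for the test of whether shared YAP peaks lay only in the regions and windows defined here, and for the test of recurring distances against small moves. The tests of peak width and weak Avruch peaks were set in their present regions after the same tests had been seen with dense windows left out. The tests of recurring distances against random placement and of dense windows were written down before their own results were seen. Both results below were singled out because the YAP antibodies differed under the same contrast, by a block bootstrap of the ratio of their ratios. Each antibody has 1 library, so a difference between antibodies is also a difference between libraries.

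The strongest 5% of TEAD1 peaks carried an Avruch peak 2.75 times as often as the next 25% (11.4% against 4.14%), and a Santa Cruz peak 5.25 times as often (8.66% against 1.65%). The ratio of these ratios, Avruch over Santa Cruz, was 0.524 (0.425 to 0.633), and it was 0.537 outside repeat-like regions (0.333 to 0.959). Clustered TEAD1 peaks carried an Avruch peak at 4.73% against 2.44% for TEAD1 peaks outside clusters, and a Santa Cruz peak at 2.61% against 0.531%. The ratio of these ratios was 0.394 (0.319 to 0.493), and it was 0.625 outside repeat-like regions (0.464 to 0.849).

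Agreement between the YAP antibodies lay mostly in repeat-like regions, and a candidate explanation is reads from multi-copy sequence that pile up whatever the antibody. Those regions are drawn partly from wide YAP peaks, so this pattern is partly set by construction. Sharing was not confined to the regions and dense windows defined here, since outside both 4.88% of Santa Cruz peaks overlapped an Avruch peak, against at most 0.687% in the local moves. Recurring distances between peaks, as tandem arrays would give, were looked for in windows dense in Avruch peaks. Random placement does not keep the blocks in which peaks lie. Against it, recurring distances were found in 9 of 43 windows with at least 50% of those peaks in repeat-like regions (20.9%, random placement itself 2.45%). They were also found in 3 of 14 other dense windows (21.4%, random placement itself 2.11%). Against moves of up to 2 kb, which keep such blocks at larger scales, they were found in 3 of the 43 (6.98%, Wilson 95% interval 2.40 to 18.6) and 2 of the 14 windows, the chromosome 4 window with 106 Avruch peaks among the latter in both comparisons, where the moves themselves gave 2.58% and 2.57%, so these counts decide neither for nor against tandem arrays. Multi-copy sequence, in these regions or missed by their definition, stays open, as do a control library common to the lists and YAP bound at these places, which no comparison here tested.

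Outside repeat-like regions, Avruch sharing was lower at the strongest 5% of TEAD1 peaks than at the next 25% (1.59% against 2.99%, ratio 0.531, 0.351 to 0.735). These regions are drawn partly from wide YAP peaks, so leaving them out acts on the sharing as well. Inside them 14.5% of TEAD1 peaks carried an Avruch peak, against 2.19% outside. Shared peaks among the strongest 5% numbered 279 in all regions and 36 outside, where the class was drawn anew. Outside these regions the ratio stayed below 1 with the higher-scoring 50% of YAP peaks (0.659, 0.404 to 0.960). This test was set after values had been seen and was not run for the strongest 10% against the rest. It therefore does not decide on weak Avruch peaks as a cause. With 200 bp windows the ratio was also below 1 (0.484, 0.32 to 0.689), but that test could not decide on peak width. TEAD1 peaks outside were widest in the highest bin (median 514 bp, against 441 bp in bin 19), so equal windows would tend to lower the ratio whatever its cause. The pattern depends on the contrast, since for the strongest 10% against the rest the ratio was 0.779 with an interval that included 1 (0.564 to 1.04). The Santa Cruz ratio was 0.990 (0.536 to 1.51) for the 5% contrast and 2.47 (1.68 to 3.40) for the 10% contrast. Dense arrays stay open, because leaving out windows dense in YAP peaks (ratio 0.495) removed 9.17% of the TEAD1 peaks shared with Avruch but 1.67% of all TEAD1 peaks and so acts on the sharing itself; background common to libraries, which may be a source of shared weak peaks, and the choice of antibody stay open too.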

How the results depend on the processing

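The restrictions by region and the contrasts of TEAD1 score were chosen after the values had been seen; the other alternatives were planned. Under the planned ones, 46 values kept their direction and side of the threshold or stayed within 1.5 times, and the overlap shares exceeded random placement in every setting run. Their size depended on the settings: Santa Cruz in Avruch ranged from 18.4% to 39.1%, Avruch in Santa Cruz from 4.50% to 24.6%, Santa Cruz in TEAD1 from 8.17% to 40%, Avruch in TEAD1 from 5.73% to 20.6%, and TEAD1 with YAP from 1.47% to 10.5%. Clustered minus single sharing for Avruch ranged from 1.11 to 6.05 percentage points. Of the values under later choices, 46 kept their direction and call or stayed within 1.5 times, 19 turned, 3 lost their call and 2 moved further. The 3 values that moved under planned choices were the numbers of peaks after keeping the higher-scoring 50%, by construction 1235, 5059 and 24481. Santa Cruz peaks also fell to 1523 outside repeat-like regions and 1456 without dense windows. Clustered minus single sharing for Avruch turned to -0.125 and -0.679 percentage points under these restrictions. The former has an interval including 0. For Santa Cruz, 2.08 became 0.207 and 0.0747, the last with an interval including 0 (-0.0598 to 0.211). The filter on dense windows removes YAP peaks that lie close together, so a sign or lost call under it is not read as a finding. Repeat-like regions are drawn partly from wide YAP peaks, so leaving them out acts on the sharing too. The cause was not tested. Avruch sharing at the strongest 5% against the next 25% turned from 2.75 to 0.531 and 0.495. Outside repeat-like regions it was also 0.484 in 200 bp windows and 0.659 for the higher-scoring 50% of YAP peaks. With dense windows left out it was 0.461 in 200 bp windows, 0.464 at 50% mutual overlap, 0.502 on autosomes, and 0.639 or 0.615 for the higher-scoring 50% of all YAP peaks or of those outside. For the strongest 10% against the rest it was 0.779 and 0.677. For Santa Cruz, 5.25 became 0.990 outside repeat-like regions, with 0.852 and 1.00 in these 2 settings, and 1.01 without dense windows, then 0.823, 0.517, 0.964, 1.02 and 0.965 in the 5 settings with dense windows left out, each with an interval including 1; the cause was not tested. For the strongest 10% against the rest, the Santa Cruz ratio stayed above 1, at 2.47 outside repeat-like regions (1.68 to 3.40) and 2.43 without dense windows (1.64 to 3.41). The planned results on start sites, motifs and gene lists were not run for want of an hg19 annotation. No paired analysis was possible because each antibody has 1 library. Unknown depth limits any comparison of peak numbers.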

Other observations

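The values in this part were not planned, and the positions named were chosen after their values had been seen. Among the autosomes and chromosome X, TEAD1 peaks outside repeat-like regions were densest on chromosome 19, with 46.7 peaks per Mb of such sequence (2374 peaks), followed by chromosome 17 with 32.2 per Mb and chromosome 22 with 29.4. Low values were found on chromosome X (8.39 per Mb), chromosome 4 (10.00) and chromosome 18 (10.3). Avruch peaks ranged from 5.99 per Mb on chromosome 19 to 1.53 on chromosome 18 and 1.57 on X. Santa Cruz peaks ranged from 1.28 per Mb on chromosome 19 to 0.255 on chromosome 18 and 0.257 on X. The Y chromosome was not included.

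Of the 100 highest-scoring TEAD1 peaks outside repeat-like regions and windows dense in YAP peaks, 2 carried a YAP peak (2%, Wilson 95% interval 0.550 to 7.00). Of all TEAD1 peaks there, 2.33% did (1036 of 44546, 2.19 to 2.47). Both were shared with the Avruch antibody, and both were among the highest 10, so the share depended on how many peaks were taken. It was 20% of the highest 10 (5.67 to 51.0) and 10% of the highest 20 (2.79 to 30.1), with intervals above 2.33%, and 4% of the highest 50 (1.10 to 13.5), with an interval that included it. These sets are nested and rest on the same 2 peaks. Both filters act on YAP sharing, since they are drawn wholly or partly from YAP peaks. In all regions, the highest of 20 TEAD1 score bins shared 11.4% with Avruch and 8.66% with Santa Cruz. The 2 shared peaks lay on chromosome 14 (62221782 to 62222495, score 3100) and chromosome 10 (47152496 to 47153106, score 2982.74). The former held the highest-scoring Avruch peak outside these regions (62221974 to 62222285, score 480.26). TEAD1 peaks with high scores and no YAP peak included chromosome 4 (84128740 to 84129456, score 3100), chromosome 7 (43733435 to 43734101, score 3100) and chromosome 6 (132272198 to 132272901, score 3039.45). They also included 2 peaks near the shared peak on chromosome 10 (47767896 to 47768545, score 2821.44, and 48276308 to 48276873, score 2779.44). Whether these chromosome 10 peaks are separate sites was not tested.

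Outside repeat-like regions, 64 TEAD1 peaks overlapped both YAP lists. With dense windows also left out, the highest-scoring lay on chromosome 19 (3649103 to 3650035), with a TEAD1 score of 530.0, and on chromosome 11 (134709214 to 134709873), with a score of 469.4. The highest-scoring Santa Cruz peak outside lay on chromosome 1 (11889529 to 11889760, score 282.0) and overlapped both other lists. Where peaks overlapped there, the distance from the peak centre to the nearest centre in the other list had a median of 49.5 bp for Avruch with TEAD1 (904 peaks), 56.5 bp for Santa Cruz with TEAD1 (190 peaks) and 31.0 bp for Santa Cruz with Avruch (71 peaks). Overlap by itself keeps these distances short, and no random value was computed, so they do not show that the centres coincide more than overlap requires.

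On the autosomes and chromosome X, 16 Avruch peaks outside these regions had a score of at least 150 and no TEAD1 peak. The highest lay on chromosome 1 (7174813 to 7175675, score 471.6). Another 3 stood near each other on chromosome 11, at 101981698 to 101981922 (score 155.4), 101984877 to 101985126 (score 192.9) and 102100441 to 102100678 (score 200). None of these 3 overlapped a Santa Cruz peak, which was also true of most of the 16. Genes were not annotated here, so whether these 3 peaks lie in exons of a gene, as copies of a cDNA introduced into the cells would give, was not tested.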
